A study of Homo sapiens with 6 samples.

How the data were processed

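RNA-seq gene expression was measured in 6 libraries of Mum-2b, a human uveal melanoma cell line. Per the labels, 3 libraries came from control cells of wild-type genotype and 3 from cells in which NELFCD was knocked down with a short hairpin RNA (shRNA). The knockdown titles carry a single hairpin number, so effects of the target and of that hairpin's off-targets were not separable in this design. Total RNA was extracted with either of 2 kits, TRNzol Universal Reagent or Quick-RNA MiniPrep, and libraries were made with the SMARTER mRNA-seq Library Prep Kit, per the labels' protocols. Which library used which extraction kit was not given. The labels did not say whether equal replicate numbers shared a day or a culture, or whether the replicates were separate cultures.

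The deposited count table holds raw counts per gene for each library, with Ensembl gene identifiers, symbols, coordinates, lengths and biotypes, per the file headers. The genome build was hg38, per the submitters' processing notes. The aligner, the counting program and whether counting used strand were not given. The deposited FPKM table, which scales fragments by gene length and library depth, was checked against the counts. Each FPKM value equalled the count divided by the gene length and by 1 constant per library, and that constant was 0.9816 to 1.0735 times the sum of the library's counts. Gene coordinates and lengths in the deposited table matched GENCODE release 29.

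Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1, DESeq2 1.42.0). Genes were filtered by filterByExpr on the groups, which left 14844 genes. Trimmed mean of M-values (TMM) factors were 0.989 to 1.034. Quasi-likelihood F-tests (glmQLFit with robust estimation) were adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p under 0.05. Counts-per-million values (CPM) were computed on the TMM-scaled library sizes. Groups are described by the mean and sample standard deviation (SD) over 3 libraries, and log2 fold changes carry their standard error (SE). Depth was 14306733 to 16656630 counts per library, and 95% Poisson intervals around a single library's CPM cover counting error only, since reads without molecular identifiers are not independent molecules.

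The design chosen before the data were examined compared 3 knockdown with 3 control libraries without a replicate term, and the same fit with the replicate number as a block was planned as an alternative. The groups share the numbers 1 to 3, and same-numbered libraries deviated together from their group means, with correlations across genes of 0.838, 0.629 and 0.616 for numbers 1, 2 and 3. By that measure the numbers paired the samples. The pairing came from the data and not from the labels, and it rested on number 1, because the difference between replicates 2 and 3 was uncorrelated between the groups (-0.005). The common biological coefficient of variation was 32.6% without the block and 8.2% with it, with 4 and 2 residual degrees of freedom. Camera results stand with and without the block wherever the block changed a list call. Log2 fold changes of genes and counts of list members are from the blocked fit unless stated, as edgeR called 0 genes without it. Adjusted over the list alone without the block, 3 histone genes rose and 2 fell, and 2 extracellular matrix genes fell. No other list had more than 2 such calls. Replicate 1 as a batch term, replicates 2 and 3 alone, and blocked fits with other scalings, filters, tools, corrections and left-out pairs were added after the data were seen.

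A total of 34 gene lists with 857 memberships and 839 different genes were fixed before the data were examined, and 853 memberships matched the table by gene identifier. The 32 lists with at least 3 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over all lists tested. Camera with an estimated correlation and the self-contained test fry were run as alternatives. With few residual degrees of freedom (4 without the block, 2 with it), camera with an estimated correlation called 0 lists in each contrast it was run on. That held even for replicate 1 against replicates 2 and 3, where 45 of 46 DNA replication genes were lower. A list that it did not call is therefore not shown to be unchanged. Counts of members that rose or fell are given with p adjusted over all genes, and also adjusted over the list alone. Genes were named by a rule fixed in advance. It took the 4 NELF subunits and, among protein-coding genes past the threshold with at least 10 CPM in the higher group and groups that did not overlap, the 12 largest rises and the 12 largest falls. It further took the 2 genes with the smallest p in each direction and, per list, up to 4 passing members with the largest fold change at 1 CPM or more and up to 2 that did not pass, those of highest expression. edgeR, the tool chosen for the tests, called no gene without the block (DESeq2 called 74), so the parts of the rule that need a call were applied to the blocked fit. Genes named outside the rule are marked as chosen after their values were seen.

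The fits were tested on simulated data that used the means, library sizes and spread of these libraries over 14844 genes. Without the block the fit recovered 0% of genes changed 1.5-fold, 0% of those changed 2-fold and 21.2% of those changed 4-fold. With the block it recovered 70.1%, 80.6% and 97%, and unchanged genes made up 4.7% of the blocked calls. The simulation gave same-numbered libraries the same means, took its spread from the blocked fit and set equal changes in every pair. The blocked model therefore held by construction, so these values apply only where the inferred pairing and equal effects hold. Camera called the shifted list in both fits and 0 of 20 unchanged lists. Genes were simulated independently of each other, so this could not show false list calls that arise from correlated genes. Principal components were computed on log2 CPM with a prior count of 2. For NELFCD alone, an exact two-sided permutation test over 20 regroupings was run. Alternatives covered other normalizations (DESeq2 size factors, upper quartile), filters, gene length and GC trends removed by lowess offsets (span 0.3), DESeq2, limma-voom, limma on log2 FPKM with pseudocounts of 1 and 0.1, and each library left out. GC content was known for 14840 of the 14844 tested genes. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3. The lists for blood cells and for genes high in class 2 uveal melanoma had too few tested members and were not tested.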

Results

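Gene expression was compared between Mum-2b uveal melanoma cells with NELFCD knocked down by an shRNA (n = 3) and control cells (n = 3). NELFCD is a subunit of the negative elongation factor (NELF), which holds RNA polymerase II in a pause soon after transcription starts. The series title ties NELFCD to the proliferation of these tumour cells, and the comparison asks which transcripts differ when it is depleted. Total counts were 14776536, 14306733 and 16106948 in control libraries 1 to 3 and 14600333, 16656630 and 14627832 in knockdown libraries 1 to 3. Between 23414 and 25846 genes had at least 1 count per library, protein-coding genes took 96.7% to 97.7% of the counts, and 14844 genes were tested.

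NELFCD was left at 41.5% of its control level in the knockdown. With the replicate number in the model, the protease inhibitor gene SERPINB2, the guanine deaminase gene GDA and the YAP target ANKRD1 rose, and the collagen chain COL6A1, the growth factor PDGFB, the vascular cadherin CDH5 and cyclin D1 (CCND1) fell. As groups, genes of DNA replication, mitosis and the integrated stress response were lower, and genes of ribosomes and the respiratory chain were higher. ER chaperone genes were lower in replicate pairs 2 and 3 but not in pair 1 (medians -0.35, -0.30 and 0.02). Extracellular matrix genes moved in both directions, with more falls than rises (median -0.09). These group calls held at camera's preset correlation, and none held with an estimated one. Camera with an estimated correlation called 0 lists in each contrast it was run on. The largest of the single-gene changes exceeded 4-fold, while the group medians of the blocked fit stayed within 0.30 log2 of 0. Replicate 1 of both groups differed from replicates 2 and 3 in most genes, and edgeR called no gene without the replicate number in the model.

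NELFCD (ENSG00000101158, chromosome 20, 58981208 to 58995133, hg38) was lower in each of the 3 knockdown libraries than in any control library. Its level was 65.5, 88.3 and 83.5 CPM in control replicates 1 to 3 and 20.7, 37.4 and 40.3 CPM in knockdown replicates 1 to 3. The mean went from 79.1 ± 12 (SD, n = 3) to 32.8 ± 10.6 CPM (SD, n = 3), which left 41.5% of the control level. By replicate pair, 31.7%, 42.5% and 48.3% of NELFCD remained. Raw counts were 956, 1248 and 1336 in the controls and 311, 618 and 588 in the knockdowns, and the 95% Poisson interval of the lowest control library (60.7 to 68.9 CPM of total counts) lay above that of the highest knockdown library (37.0 to 43.6). The deposited FPKM was 12.54 ± 2.06 in controls and 5.15 ± 1.75 in knockdowns (SD, n = 3). The exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold change was -1.27 without the replicate block (adjusted p = 0.53) and -1.303 ± 0.109 (SE) with it (adjusted p = 0.00046), and over 30 alternatives the adjusted p ran from 3.9e-68 to 1. The other NELF subunits did not pass in edgeR's blocked fit, with log2 fold changes of -0.02 for NELFA (adjusted p = 0.92), -0.14 for NELFB (adjusted p = 0.17) and 0.14 for NELFE (adjusted p = 0.2). The complex as a list of 4, with the target in it, had a camera adjusted p of 0.044 with the block and 0.23 without it, and a blocked adjusted p = 0.64 with an estimated correlation. Its blocked call was lost with no filter (0.067) and at a mean of at least 5 CPM (0.13). Of 7 tested genes that neighbour NELFCD on the chromosome 0 passed in edgeR's blocked fit, 1 rise and 1 fall had an unadjusted p under 0.05, and DESeq2 and limma-voom with the block called 0, while in replicates 2 and 3 alone edgeR called 1 rise and 3 falls.

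**Figure D1:**
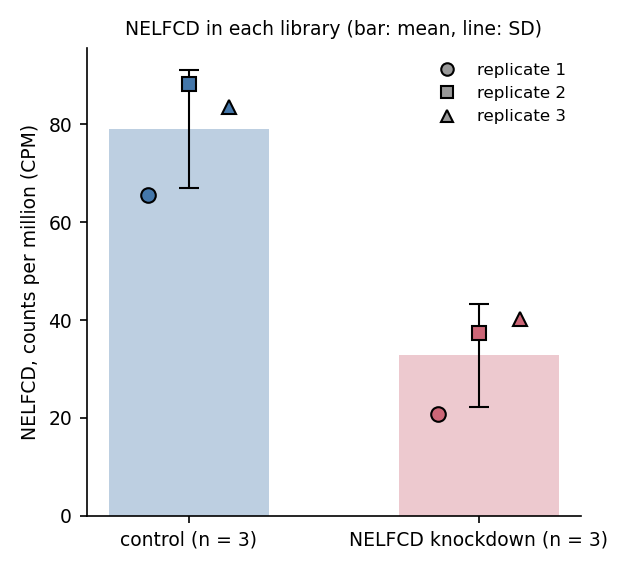
NELFCD in CPM in each library, with bars for the group means and lines for the SD (n = 3). The controls lay between 65.5 and 88.3 CPM and the knockdowns between 20.7 and 40.3 CPM.

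The libraries parted first by replicate number and then by group. Replicate 1 of both groups lay apart from replicates 2 and 3 on the first principal component (68.8% of variance), and the groups lay apart on the second (17.1%). Replicate 1 carried less of the DNA replication and mitosis genes and more of the NF-kB and interferon genes, with list medians on the log2 scale of -1.60 and -1.37 against 1.62 and 1.22. Of their members 45 of 46 and 39 of 39 were lower there, and 21 of 21 and 25 of 30 higher, in edgeR (camera adjusted p of 1.5e-49, 4.6e-42, 3.6e-20 and 1.5e-09, and adjusted p = 0.12, 0.13, 0.12 and 0.18 with an estimated correlation). In total 9170 of 14844 genes differed between replicate 1 and replicates 2 and 3 in edgeR's fit with both group and replicate 1 as terms. Replicates 2 and 3 of a group differed by a chi-square per degree of freedom of 2.23 in controls and 2.09 in knockdowns, where counting noise alone gives 1, against 98.9 to 115 for replicate 1 against either. The p-values in replicates 2 and 3 alone and of the interaction with replicate 1 rest on that small spread. Those of the fits with the block or the batch term rest on it in part. Their error also holds the disagreement of pair 1 with pairs 2 and 3. The labels do not say whether replicates 2 and 3 were separate cultures.

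**Figure D2:**
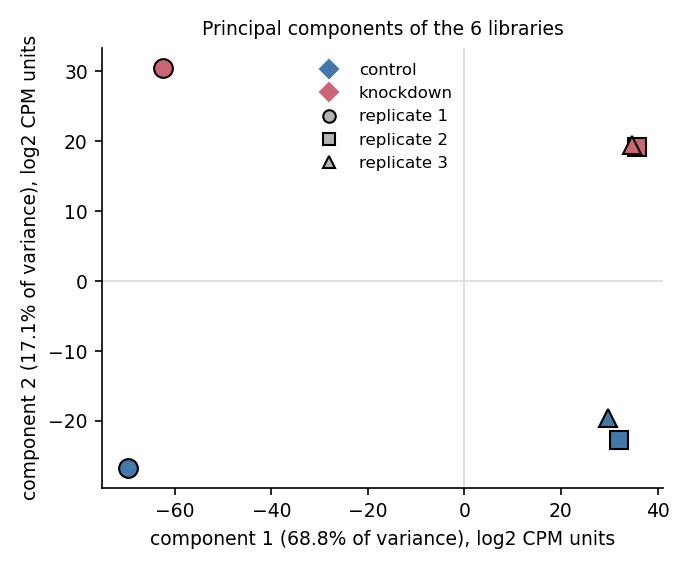
The first 2 principal components of log2 CPM over the tested genes, with 1 point per library, colour for the group and shape for the replicate number. Component 1 (68.8% of variance) separates replicate 1 of both groups and component 2 (17.1%) separates knockdown from control.

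Across the transcriptome, 813 genes rose and 1189 fell in the knockdown when the replicate number was in the model, 2002 of 14844 genes (13.5%), and 128 of the rises and 132 of the falls were at least 2-fold. Without the replicate block edgeR called 0 genes changed, with 954 at an unadjusted p under 0.05 where 742 were expected by chance (smallest adjusted p = 0.088, GDA). Without a block DESeq2 called 74 genes and limma-voom 0. Within the 2 replicates that resemble each other (2 and 3 alone) 1732 genes rose and 2026 fell, 3758 of 14836. Of the blocked calls 1949 were also called there, in a fit that shares 4 of the 6 libraries, and 3318 of 3740 genes called in replicates 2 and 3 (88.7%, chance 50%) had the same sign in pair 1, which that test did not use. The 2 left-out pairs that moved the blocked count most were pair 2 (932 genes without it) and pair 1 (4090 without it). The blocked split was 40.6% rising with TMM, and over the blocked alternatives it ran from 27.3% (DESeq2) to 54.9% (upper-quartile scaling), where the median of all genes moved by 0.048 log2.

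SERPINB2, GDA, TLL2 and ANKRD1 were among the genes with the largest rises. SERPINB2 (ENSG00000197632, chromosome 18, 63871692 to 63903890), which encodes the plasminogen activator inhibitor PAI-2, went from 2.51 ± 1.70 to 41.8 ± 28.97 CPM (SD, n = 3), a log2 fold change of 4.05 ± 0.123 (SE). GDA (ENSG00000119125, chromosome 9, 72114595 to 72257193), the guanine deaminase, went from 160 ± 10.6 to 530 ± 11.4 CPM (SD, n = 3), a log2 fold change of 1.73 ± 0.066 (SE), and had the smallest p of all genes without the block. TLL2, a tolloid-like protease, rose from 2.10 to 12.4 CPM (log2 fold change 2.59), and ANKRD1, a YAP target, rose from 5.80 to 27.0 CPM (2.25). The protease ADAMTS9 (1.92), the NKG2D ligand RAET1E (1.71), the laminin chain LAMA4 (1.44), the peptide hormone adrenomedullin ADM (1.22) and the ectopeptidase TRHDE (1.20) followed. SRPX2 (1.14), STAC (1.13) and the extracellular matrix protein SVEP1 (1.07) completed the 12. Their adjusted p in edgeR's blocked quasi-likelihood fit (Benjamini-Hochberg) ran from 2.4e-06 for SERPINB2 to 0.022 for LAMA4. In edgeR's fit without the block it ran from 0.088 for GDA to 0.59 for TRHDE. Exons of SERPINB2 (19.9%), RAET1E (37.2%) and SRPX2 (17.2%) overlap another gene, so part of their counts is uncertain.

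COL6A1, SLC14A1, PLXND1 and AKR1C2 were among the genes with the largest falls. COL6A1 (ENSG00000142156, chromosome 21, 45981737 to 46005050), a collagen VI chain, went from 149 ± 114 to 30.9 ± 20.6 CPM (SD, n = 3), a log2 fold change of -2.22 ± 0.076 (SE). PDGFB, a platelet-derived growth factor chain, fell from 47.8 to 14.1 CPM (log2 fold change -1.73), and the Wnt ligands WNT7B (-1.68) and WNT5B (-1.51) fell as well. The urea transporter SLC14A1 (-2.001), the semaphorin receptor PLXND1 (-1.95), the kinase PIM1 (-1.76), PRR15 (-1.47) and SH3BP4 (-1.41) also fell. The aldo-keto reductases AKR1C2 (-1.79) and AKR1C1 (-1.59) fell, though near-identical paralogs leave the division of their reads uncertain. Falls with the smallest p were the vascular cadherin CDH5 and the Polycomb component PCGF5 without the block, and COL6A1 and CCDC80 with it. Blocked log2 fold changes were -1.38 ± 0.091 (SE) for CDH5, -0.96 ± 0.066 (SE) for PCGF5 and -1.46 for CCDC80. The CCDC80 groups overlapped, as control replicate 1 (66.5 CPM) lay below knockdown replicates 2 and 3 (110 and 106 CPM). Its adjusted p in edgeR's fit without the block was 0.87. The adjusted p of the 12 falls in edgeR's blocked fit ran from 3.4e-06 for COL6A1 to 0.042 for WNT7B. In edgeR's fit without the block it ran from 0.49 for SH3BP4 to 0.79 for WNT5B. Of the 12 falls 11 are named here. Of 14 fits that kept the replicate number in the model or left replicate 1 out, WNT7B passed in 8 (largest adjusted p 0.49), and the 12 rises and the other 10 of these 11 falls each passed in 14. WNT7B lost the blocked edgeR call without pair 2 (adjusted p = 0.26) and without pair 3 (adjusted p = 0.16).

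**Figure D3:**
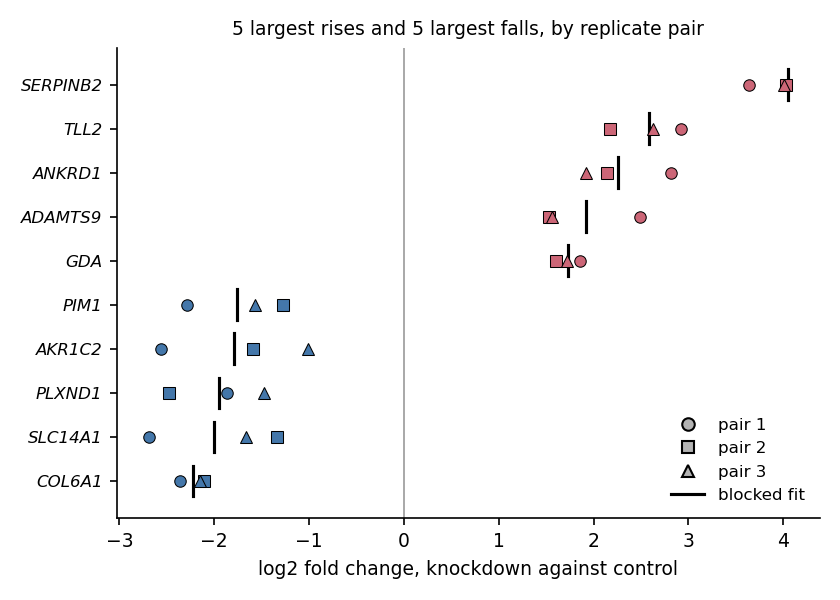
Log2 fold change, knockdown against control, as 1 point per replicate pair and a bar for the blocked fit. Shown are the 5 largest rises and the 5 largest falls among protein-coding genes called with the block. Only genes with at least 10 CPM in the higher group and groups that did not overlap were ranked. SERPINB2 (4.05) had the largest blocked rise of these genes and COL6A1 (-2.22) the largest blocked fall.

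Genes of DNA replication and mitosis were lower in the knockdown. Of 46 DNA replication and G1/S genes 14 fell and 0 rose over all genes tested, and 24 fell adjusted over the list alone. The E2F transcription factors E2F8 (log2 fold change -0.81), E2F2 (-0.51) and E2F1 (-0.50) fell, as did the replicative helicase subunit MCM6 (-0.49). MCM4 (-0.25) and RRM1 (-0.06) did not pass. The list median was -0.24, and -0.44, -0.16 and -0.17 in pairs 1 to 3. Of 39 mitosis and G2/M genes 6 fell and 0 rose, or 8 fell and 1 rose adjusted over the list alone, with a median of -0.13. The spindle motor KIF11 (-0.55), HMMR (-0.38), MYBL2 (-0.37) and the kinase AURKB (-0.31) fell, and TOP2A (-0.15) and ANLN (-0.20) did not pass. Of 22 homologous recombination and DNA damage response genes 5 fell and 1 rose, or 9 fell and 1 rose adjusted over the list alone, with BRIP1 (-0.43), TIMELESS (-0.37), BRCA1 (-0.35) and CLSPN (-0.32) the largest falls, while TOPBP1 (-0.20) and ATM (0.05) did not pass. CHEK1 (-0.24) and ATR (0.22), chosen after their values were seen, completed those that fell and rose. Camera with the block gave an adjusted p of 7.6e-07 for DNA replication, 0.003 for mitosis and 0.02 for homologous recombination, and an adjusted p = 0.64 with an estimated correlation for each of the 3. Camera without the block gave 0.097, 0.24 and 0.32. Without knockdown replicate 1 the unblocked medians turned to 0.174, 0.245 and 0.133 (camera adjusted p 0.018, 0.0053 and 0.23, upward), and without control replicate 1 they were -0.544, -0.396 and -0.441. These lists are also those that lay lowest in replicate 1 of both groups, and camera in replicates 2 and 3 alone gave an adjusted p of 7.9e-07 for DNA replication, 0.0081 for mitosis and 0.067 for homologous recombination. The blocked homologous recombination call was also lost without pair 1 (camera adjusted p = 0.055, range 7.8e-05 to 0.98 over 26 alternatives), with the length trend removed (0.063) and at a mean of at least 5 CPM (0.076). Of 6 CDK inhibitor genes 0 passed in edgeR's blocked fit, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom with the block called 0, while in replicates 2 and 3 alone 1 rose and 1 fell. CDKN1A was at -0.001 and CDKN1B at -0.05, and the list median of -0.04 turned to 0.01 with upper-quartile scaling (blocked camera adjusted p = 0.71).

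Extracellular matrix and mesenchymal genes moved in both directions, with more falls than rises. Of 38 extracellular matrix and mesenchymal genes 12 fell and 4 rose over all genes, or 17 fell and 4 rose adjusted over the list alone. The falls were led by the collagen chains COL6A1, COL5A1 (-1.93) and COL6A2 (-1.54) and the matrix protease MMP2 (-1.91). Chosen after their values were seen, the urokinase gene PLAU fell from 534 to 320 CPM (-0.74) and the membrane protease MMP14 fell by 0.68. The rises were LAMA4 and, likewise chosen after their values were seen, tenascin C TNC (0.92), TGFBI (0.85) and LAMB1 (0.26). VIM (-0.06) and TGM2 (0.16) did not pass. The list median was -0.09 (-0.376, -0.06 and -0.056 in pairs 1 to 3) and its mean -0.33. In replicate 1 of both groups 21 members lay higher and 4 lower (camera adjusted p of 0.0055, and an adjusted p = 0.31 with an estimated correlation), and the unblocked median of -0.123 moved to -0.016 without control replicate 1. Camera gave an adjusted p of 2.0e-05 with the block and 0.02 without it, but an adjusted p = 0.64 with an estimated correlation in the blocked test and 0.90 in the unblocked test. The unblocked call was lost without control replicate 1 (camera adjusted p = 0.37), knockdown replicate 2 (0.058) or knockdown replicate 3 (0.053). It was also lost at a mean of at least 5 CPM (0.21), with the length trend removed (0.055) and on log2 FPKM with a pseudocount of 1 (0.093) or 0.1 (0.11).

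Integrated stress response genes were lower, and ER chaperone and interferon genes were lower in pairs 2 and 3 but not clearly in pair 1. Of 22 integrated stress response genes 9 fell and 1 rose, or 11 fell and 2 rose adjusted over the list alone, with a median of -0.28. This list lay higher in replicate 1 by a median of 1.14, in 21 of 22 members (camera adjusted p of 8.9e-20, and an adjusted p = 0.065 with an estimated correlation). Its unblocked median of -0.22 moved to 0.365 without control replicate 1 and to -0.74 without knockdown replicate 1. The rise, chosen after its values were seen, was STC2 (0.45). DDIT4 (-0.90, 41% of its exons shared with another gene), CHAC1 (-0.64), SESN2 (-0.63) and the serine synthesis enzyme PHGDH (-0.54) fell, while the regulator ATF4 (-0.15) and the transporter SLC7A5 (0.08) did not pass. Of 20 ER chaperone and unfolded protein response genes 7 fell and 0 rose, or 9 fell adjusted over the list alone. DNAJB9 (-0.68), DNAJB11 (-0.43), SYVN1 (-0.35) and DNAJC3 (-0.32) fell, and CANX (0.07) and HSP90B1 (-0.39) did not pass. The ER list median was 0.02 in pair 1 and -0.35 and -0.30 in pairs 2 and 3. Of 30 type I interferon response genes 5 fell and 0 rose, the same counts as adjusted over the list alone, with DDX60 (-0.83), HERC5 (-0.81), OASL (-0.77) and PARP14 (-0.49) the largest falls. IFIH1 (-0.48), chosen after its values were seen, was the other fall, and LGALS3BP (0.16) did not pass. The interferon median was -0.03 in pair 1 and -0.28 and -0.33 in pairs 2 and 3. Camera with the block gave an adjusted p of 0.0039 for the integrated stress response, 0.0017 for ER chaperones and 0.0086 for interferon genes, each with an adjusted p = 0.64 with an estimated correlation. Camera without the block gave 0.38, 0.051 and 0.18, and the blocked interferon call was lost without pair 3 (camera adjusted p = 0.16, range 1.5e-08 to 0.89 over 26 alternatives) and at a mean of at least 5 CPM (0.055). The unblocked interferon median of -0.115 moved to 0.332 without control replicate 1 and to -0.819 without knockdown replicate 1.

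MAPK pathway output genes were lower and ribosome and respiratory chain genes higher. Of 20 MAPK pathway output genes 5 fell and 2 rose, or 9 fell and 2 rose adjusted over the list alone, with a median of -0.13. Cyclin D1, CCND1, fell from 722 to 386 CPM (-0.96), EGR1 (-0.77) and PHLDA1 (-0.38) fell, and the feedback inhibitor SPRY1 rose (1.06). EMP1 (0.03) and FOSL1 (0.07) did not pass. Chosen after their values were seen, SPRED2 (-0.36) and DUSP5 (-0.34) were the other falls, and MYC rose from 293 to 379 CPM (0.37). Of 30 ribosome biogenesis genes 3 rose and 1 fell, or 14 rose and 1 fell adjusted over the list alone, with NOP16 (0.35), RRP9 (0.34) and NIP7 (0.28) rising and NAT10 (-0.28) falling. This list lay lower in replicate 1 by a median of 0.726, in 28 of 30 members (camera adjusted p of 2.5e-13, and an adjusted p = 0.195 with an estimated correlation). Its unblocked median of 0.159 moved to -0.077 without control replicate 1 and to 0.342 without knockdown replicate 1, and that of MAPK output moved from -0.126 to 0.14 without control replicate 1. MAPK output genes lay higher in replicate 1 in 11 of 20 members and lower in 5 (camera adjusted p of 0.0091, and an adjusted p = 0.195 with an estimated correlation). Of 75 cytosolic ribosomal protein genes 8 rose and 1 fell, or 17 rose and 1 fell adjusted over the list alone, with RPS13 (0.32) and RPL29 (0.29) rising, RPL22 (-0.30) falling, and RPL4 (0.15) and RPL8 (0.14) not passing. Ribosomal protein genes lay higher in replicate 1 in 41 of 75 members and lower in 6 (camera adjusted p of 0.045, and an adjusted p = 0.81 with an estimated correlation). Of 44 nuclear respiratory chain genes 7 rose and 0 fell, also 7 adjusted over the list alone, among them NDUFB3 (0.50), ATP5MC1 (0.38), NDUFB10 (0.37) and ATP5F1D (0.31). In replicate 1 of both groups 30 of the 44 lay lower and 2 higher (camera adjusted p of 0.001, and an adjusted p = 0.33 with an estimated correlation), and the unblocked median of 0.111 moved to 0.021 without control replicate 1 (camera adjusted p = 0.86). Camera with the block gave an adjusted p of 0.041 for MAPK output, 0.00018 for ribosome biogenesis, 0.00018 for ribosomal proteins and 0.0086 for the respiratory chain, each with an adjusted p = 0.64 with an estimated correlation. Camera without the block gave 0.31, 0.051, 0.0025 and 0.07, and the unblocked ribosomal protein call was lost without knockdown replicate 1 (camera adjusted p = 0.41), with the length trend removed (0.055) and with an estimated correlation (adjusted p = 0.90). The blocked MAPK call was lost with upper-quartile scaling (camera adjusted p = 0.054, range 0.0067 to 0.94 over 26 alternatives), and the blocked respiratory chain call with the length trend removed (0.098, range 0.00053 to 0.86).

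**Figure D4:**
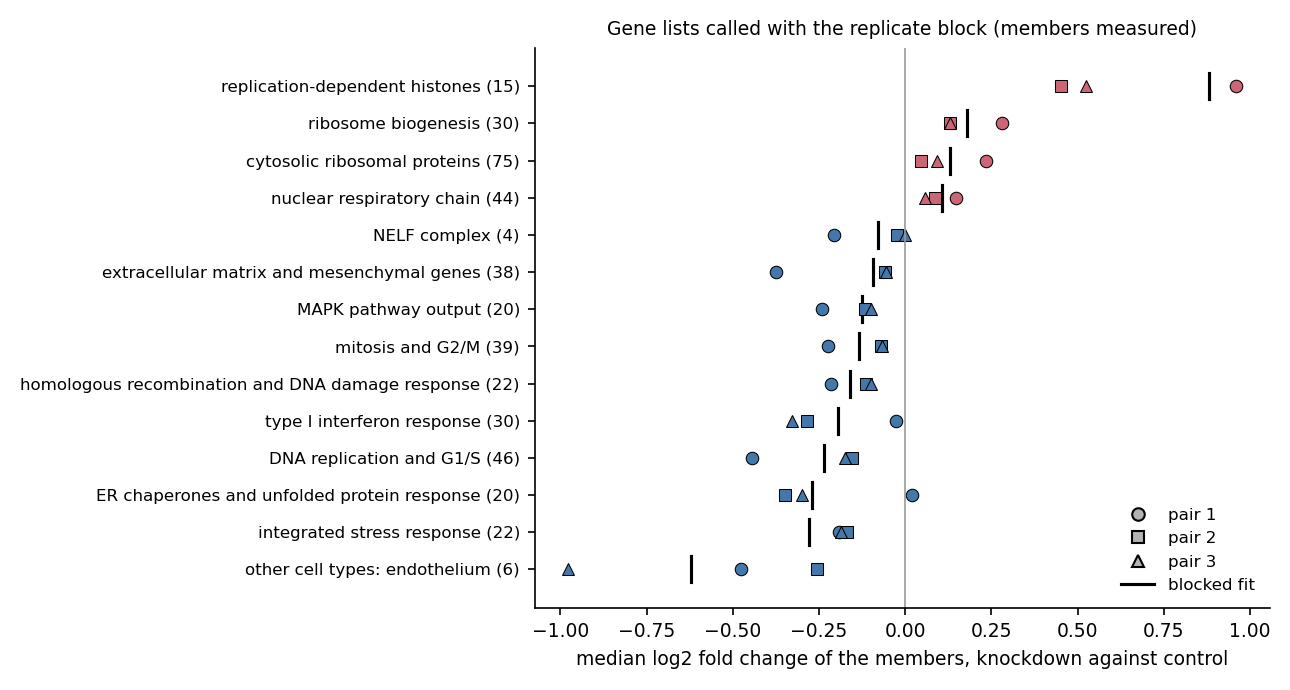
Median log2 fold change of the members, knockdown against control, for the 14 lists called by camera with the block, as 1 point per replicate pair and a bar for the blocked fit, with the number of measured members in brackets. The DNA replication median was -0.24 in the blocked fit and the ribosome biogenesis median 0.18.

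Genes of the pausing machinery and immediate early genes moved in both directions. Of 35 pausing and elongation factors 5 fell and 2 rose, with the same counts adjusted over the list alone. The falls were led by POLR2M (-0.58), EAF1 (-0.49), the Integrator subunit INTS6 (-0.43) and the elongation factor ELL2 (-0.40), while TCEA1 (-0.20) and SUPT16H (-0.01) did not pass. POLR2A (-0.26), CTR9 (0.25) and SUPT5H (0.22), chosen after their values were seen, completed the falls and rises. The list was not called (camera adjusted p = 0.25 with the block, but 0.0185 with no filter, downward), and its median of -0.03 turned to 0.02 with upper-quartile scaling. Of 29 immediate early genes 9 fell and 2 rose, or 11 fell and 5 rose adjusted over the list alone. EGR1 (-0.77), JUN (-0.53), GADD45B (-0.43) and ATF3 (-0.40) fell, the rises, chosen after their values were seen, were MYC (0.37) and KLF6 (0.38), and the list was not called (camera adjusted p = 0.12 with the block). It was called downward with the block and the length trend removed (0.027), no filter (0.0084) or pair 2 left out (0.035). Of 56 replication-dependent histone genes 15 were tested, at low levels. HIST1H4H rose (2.28, from 0.33 to 1.63 CPM) and HIST1H2BD rose (1.49), whereas HIST1H2BK (-1.04) and HIST1H4I (-0.98) fell, or 9 rose and 2 fell adjusted over the list alone. Camera gave the histone list an adjusted p of 0.00015 without the block and 0.016 with it, upward in each, with an adjusted p = 0.90 and an adjusted p = 0.64 with an estimated correlation. In replicates 2 and 3 alone the histone list was not called (camera adjusted p = 0.30, range 1.4e-06 to 0.70 over 26 alternatives), nor at a mean of at least 5 CPM with the block (0.70) or without it (0.48).

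Survival and inflammatory genes were mixed. Of 28 apoptosis regulators 4 fell and 2 rose, or 5 fell and 2 rose adjusted over the list alone. The BH3-only genes BBC3 (-1.06), HRK (-0.99) and PMAIP1 (-0.68), which promote cell death, fell, and the cytochrome c gene CYCS rose (0.29). MCL1 (-0.23) and CFLAR (0.29), chosen after their values were seen, completed those counts. Of 26 p53 targets 3 fell and 1 rose, or 5 fell and 1 rose adjusted over the list alone, with BBC3, RRM2B (-0.68) and SESN2 falling and TP53I3 (0.84) rising. Of 21 NF-kB and cytokine genes 6 fell and 4 rose, or 8 fell and 4 rose adjusted over the list alone. TRAF1 (-1.45), CSF1 (-0.81) and TNF (-0.81) fell and the chemokine CXCL8 rose (0.73), as did CXCL1 (0.51), ICAM1 (0.40) and IL1A (0.27), chosen after their values were seen. Of 23 YAP targets 5 fell and 4 rose, or 9 fell and 5 rose adjusted over the list alone, with ANKRD1, F3 (0.83) and FJX1 (0.51) rising and NUAK2 (-1.29) falling. Chosen after their values were seen, PTPN14 (-0.44), MYOF (-0.32), ASAP1 (-0.31) and AMOTL2 (-0.26) also fell and CRIM1 rose (0.24). The YAP list had a median of -0.10 and a mean of 0.02. Camera called none of these 4 lists in the blocked fit, with adjusted p of 0.37, 0.25, 0.12 and 0.90. Of 12 fits that kept the replicate number or left replicate 1 out, the NF-kB list was called downward in 4 (smallest adjusted p = 0.013, without pair 3) and p53 targets in 1 (0.04998, with no filter).

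Lineage and other cell type markers were compared last. Of 24 melanocyte lineage genes 9 were expressed highly enough to test. Of these 0 passed in edgeR's blocked fit, 1 had an unadjusted p under 0.05 (down), and DESeq2 and limma-voom with the block called 0, with a list median of -0.02 that turned to 0.03 with upper-quartile scaling and a mean of 0.09. GPNMB was the highest at 32.3 CPM over all libraries, while MITF averaged 3.38 and MLANA 1.21 CPM. Among endothelial markers TIE1 averaged 266 CPM and CDH5 96.3 CPM. CDH5 fell from 140 ± 17.8 to 53.7 ± 2.95 CPM (SD, n = 3), and TIE1 (-0.18) and EGFL7 (-0.48) did not pass. The endothelial list, with 1 of 6 members falling or 4 adjusted over the list alone, had a camera adjusted p of 0.0014 with the block and 0.0071 without it, with an adjusted p = 0.64 and an adjusted p = 0.90 with an estimated correlation. Its unblocked call was lost without control replicate 1 (camera adjusted p = 0.13), with no filter (0.13) and on log2 FPKM with a pseudocount of 1 (0.061) or 0.1 (0.091), and its blocked call with no filter (camera adjusted p = 0.081, range 2.1e-05 to 0.15 over 26 alternatives). Of 3 epithelial markers CLDN4 fell from 50.5 to 19.3 CPM (-1.40) and KRT18 rose (0.49), with KRT8 (0.21) not passing, and of 3 fibroblast markers FAP fell (-0.91). These lists were not called in the blocked fit (camera adjusted p = 0.23 and 0.43), and the epithelial median of 0.21 and mean of -0.23 differed in sign. Of the blood markers LAPTM5 averaged 67.7 CPM, and each of the other 9 stayed below 1 CPM in every library.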

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

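The interaction test, the test of added reads in replicate 1 and the test of lists that moved less in pair 1 were chosen only after the result was seen.

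The measured knockdown effect differed between replicate pair 1 and pairs 2 and 3. Pair 1 holds 1 library per group, so the spread in the interaction tests came from replicates 2 and 3 alone, which lay near counting noise (chi-square per degree of freedom 2.23 and 2.09). These tests therefore cannot show whether another replicate of pair 1 would differ in the same way. An interaction of knockdown with replicate 1 passed for 1932 of 14844 genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 751 effects higher and 1181 lower in pair 1. NELFCD itself was among them (adjusted p = 0.0029 in edgeR), with 31.7% remaining in pair 1 against 42.5% and 48.3%. The effect on ER chaperone genes was higher in pair 1 by a median of 0.18 log2 (medians 0.02, -0.35 and -0.30 in pairs 1 to 3). The effect on type I interferon genes was higher in pair 1 by a median of 0.366 (medians -0.03, -0.28 and -0.33). The DNA replication effect differed by -0.29 (medians -0.44, -0.16 and -0.17). The cytosolic ribosomal protein effect differed by 0.172 (medians 0.23, 0.05 and 0.09). The effect on mitochondrially encoded mRNAs differed by -0.374 (medians -0.25, 0.14 and 0.14). Camera on the interaction called 15 of 32 lists at the preset correlation and 0 with an estimated one, and for these 5 lists its adjusted p was 2.6e-09, 6.9e-14, 1.7e-06, 4.5e-17 and 1.9e-09, against an adjusted p = 0.30 for the first 4 and an adjusted p = 0.38 for the last with an estimated correlation. Groups of 3 libraries were not tested for outliers.

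A deeper knockdown in pair 1 was weighed against this difference. For the ER chaperone and interferon lists, which moved less in pair 1, 21 of 50 members had an interaction that passed above 0 and 3 below 0. The lists were picked for that difference, so it cannot argue against a deeper knockdown, which stays open for them. Camera with an estimated correlation did not call the difference (adjusted p = 0.30), but it called 0 lists in each contrast it was run on. The 7 lists that moved more in pair 1 were picked for a larger median there. Camera also called each of them with the block and in the interaction at the preset correlation. Their ratio of the pair 1 effect to that of pairs 2 and 3 was a median of 1.86 times the same ratio of NELFCD (1.45). A high ratio was thus selected for. Of the 7 lists, 2 lay beyond 1.5 times by more than their interval from resampled members, which left out the error of NELFCD's ratio. The interval of the ratio itself ran from -45.84 to 44.32 for extracellular matrix genes, from -17.23 to 33.73 for MAPK output and from 0.72 to 6.41 for histones. For both sets of lists a deeper knockdown and a state of the replicate 1 cells that may change the response cannot be told apart, because both belong to the same single pair.

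Replicate 1 of both groups stood apart from replicates 2 and 3, with 9170 genes that differed. Gene length and GC trends were argued against, since 9125 genes, 99.5% of that number, differed with both trends removed, 8417 of them among the 9170. Genomic DNA or unspliced RNA added to replicate 1 was argued against as the whole cause, since 612 of 9428 genes at 10 CPM or more fell by more than 2-fold there, although reads on olfactory receptor genes were 1.47 and 1.82 times as frequent in replicate 1 of the controls and knockdowns. No biological explanation was tested, as the design names none. A different culture, day or extraction kit for replicate 1 may account for the split and stays open, because the labels give none of these per library.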

How the results depend on the processing

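The fit on replicates 2 and 3, the batch term, and the blocked fits other than the block alone and the block with the length trend removed were chosen only after the result was seen. A value counted as reversed only where its direction changed and either fit passed. Changes of direction between values that did not pass counted as unchanged. NELFA, for example, was at -0.021 in the unblocked fit and at 0.026 with the upper quartile. Of 900 values of named genes under alternatives, 512 were unchanged in this sense, 388 passed where the unblocked fit did not, and 0 reversed. Of 828 values of gene lists, 642 were unchanged in this sense, 163 passed, 20 no longer passed and 3 reversed. Heat shock turned to -0.197 without control replicate 1 (highest 0.298, without knockdown replicate 1). DNA replication and mitosis turned to 0.174 and 0.245 without knockdown replicate 1 (lowest -0.544 and -0.396, without control replicate 1). Each of these fits leaves the other replicate 1 library in 1 group only, and these lists lie low in replicate 1 (medians -0.94, -1.60 and -1.37). NELFCD stayed lower in 31 of 31 alternatives, from -1.451 to -1.029. Without each library in turn, changed genes stayed at 0 to 0, genes changed 2-fold at 0 to 0, NELFCD at -1.451 to -1.029, and the number of called lists, 4 with all libraries, moved to 7 to 12. Replicates 2 and 3 alone have 2 libraries per group.

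The numbers of changed genes, of genes changed at least 2-fold and of called lists, and the NELFCD level as a log2 fold change, were 2002, 260, 14 and -1.303 with the replicate block, against 0, 0, 4 and -1.27 without it. They were 2000, 257, 14 and -1.279 with the block and the length trend removed, 3758, 348, 13 and -1.147 in replicates 2 and 3, and 3117, 324, 14 and -1.3 with replicate 1 as a batch term. With the block they were 2040, 264, 14 and -1.313 with DESeq2 size factors, 2184, 279, 13 and -1.257 with the upper quartile, 2888, 402, 17 and -1.319 with no filter, 1807, 107, 10 and -1.288 at a mean of 5 CPM or more, and 2043, 266, 14 and -1.335 with the GC trend removed. With pair 2 left out of the block they were 932, 246, 16 and -1.345, with pair 3 left out 1760, 368, 14 and -1.446, and with pair 1 left out 4090, 347, 13 and -1.147. Changed genes, 2-fold changes and NELFCD were 74, 49 and -1.289 with DESeq2 without a block, 1304, 175 and -1.334 with DESeq2 and the block, and 2130, 281 and -1.288 with limma-voom and the block. The block removes the replicate 1 difference from the error, which lowers the coefficient of variation from 32.6% to 8.2%. For the other moves the cause was not tested. The 4 lists called without the block were also called with it, and the block changed no camera list call other than those given.

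Without the block, the number of called lists was 8 with the upper quartile, 7 with no filter, 4 at a mean of at least 5 CPM (2 of them the same lists), 2 with the length trend removed, 2 on log2 FPKM with a pseudocount of 1 and 2 with 0.1, 2 with lists limited to members of at least 5 CPM, 0 with an estimated correlation and 0 with directional fry. With the block it was 0 with an estimated correlation, 1 with directional fry and 18 with mixed fry, which does not compare a list with other genes. Of the 14 lists called with the block, 7 were called in all 12 fits that kept the replicate number or left replicate 1 out: DNA replication, mitosis, integrated stress response, ER chaperones, extracellular matrix, ribosome biogenesis and ribosomal proteins. MAPK output, the respiratory chain and endothelium were called in 11, interferon and the NELF complex in 10, histones in 9 and homologous recombination in 8.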

Other observations

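The test of genomic DNA in the knockdown libraries was chosen only after the result was seen.

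Non-coding genes moved mainly upward in the knockdown. Of 1792 tested non-coding genes (long non-coding, antisense and related biotypes) 107 rose and 12 fell with the block, 89.9% rising, against 36.5% of the protein-coding calls (674 rose, 1172 fell; Fisher's exact p = 5.5e-32, with genes that are not independent). Antisense genes, whose reads are uncertain because the use of strand in counting was not given, had 37 rises and 1 fall, and long intergenic RNAs 41 rises and 7 falls. Pseudogenes, which were not in this set, also rose more often than they fell. Transcribed unprocessed pseudogenes had 12 rises and 1 fall and processed pseudogenes 8 rises and 2 falls, so the direction was not particular to the non-coding set. Chosen after their values were seen, SNHG14, the host of small nucleolar RNAs in the Prader-Willi region, rose from 23.8 ± 4.89 to 62.3 ± 33.8 CPM (SD, n = 3; log2 fold change 1.30), UCA1 rose from 19.0 to 37.0 CPM (0.99), and LINC00973 rose from 12.03 to 38.6 CPM (1.75). PVT1, the neighbour of MYC, rose (0.35), and MANCR fell (-0.84). The median non-coding log2 fold change was 0.23, 0.16 and 0.20 in pairs 1 to 3, and 162 of 196 non-coding genes called in replicates 2 and 3 alone rose, 145 of them also higher in pair 1. The split was 105 and 15 with DESeq2 size factors and 135 and 10 with the upper quartile.

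Single genes of metabolism and of uveal melanoma changed, in lists that camera with the block did not call. Of 33 glycolysis and hypoxia genes 6 fell and 1 rose, or 7 fell and 2 rose adjusted over the list alone. ENO2 (-0.76), VEGFA (-0.72) and DDIT4 (-0.90) fell and ADM (1.22) rose, while PKM (0.19) did not pass. Of 23 cholesterol genes 4 fell and 0 rose, or 4 fell and 1 rose adjusted over the list alone, with INSIG1 (-0.70), SQLE (-0.25) and IDI1 (-0.25) among the falls. Of 24 autophagy and lysosome genes 3 rose and 2 fell, or 4 rose and 2 fell adjusted over the list alone: GLA (0.37), MAP1LC3B (0.32) and, chosen after its values were seen, CTSA (0.31) rose, and GABARAPL1 (-0.84) and ULK1 (-0.65) fell. Of 8 genes high in class 1 uveal melanoma, the class of lower metastatic risk, ID2 (1.40, from 0.94 to 2.48 CPM) and ROBO1 (0.53) rose, the same counts as adjusted over the list alone. Of 11 uveal melanoma driver and pathway genes TRIO fell (-0.24), or 2 fell adjusted over the list alone. Camera with the block called none of these 5 lists, with adjusted p of 0.42, 0.25, 0.59, 0.36 and 0.37, while with no filter the cholesterol list was called downward (0.032). Directional fry with the block, which does not compare a list with other genes, called the class 1 list (adjusted p = 0.021). The hypoxia, cholesterol and class 1 medians lay within 0.05 of 0 and changed sign with DESeq2 size factors or the upper quartile. Of 19 heat shock genes and 13 mitochondrially encoded mRNAs 0 passed in edgeR's blocked fit, with 3 heat shock rises, and 1 mitochondrial rise and 1 fall, at an unadjusted p under 0.05. DESeq2 and limma-voom with the block called 0, while in replicates 2 and 3 alone 3 heat shock genes rose and 1 fell and 7 mitochondrial mRNAs rose. Camera gave heat shock and mitochondrial mRNAs an adjusted p of 0.37 and 0.60 with the block and 0.43 and 0.00088 in replicates 2 and 3 alone, where the mitochondrial list was called upward. RAB31, high in class 2 tumours, was at 46.0, 28.7 and 30.9 CPM in control replicates 1 to 3. It was at 35.8, 18.4 and 19.6 CPM in knockdown replicates 1 to 3, lower in each pair, and its list was not tested.

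The rise of non-coding genes was weighed against technical sources. Genomic DNA was argued against as the main source by the rise per kilobase on olfactory receptor genes. That rise was 0.0767% of the median rise of the non-coding genes that rose, a set picked for rising. Reads on olfactory receptor genes were 1.45, 1.34 and 1.05 times as frequent in the knockdown in pairs 1 to 3. Unspliced or overlapping reads were argued against as the whole cause by the rising shares. These were 84.8% outside protein-coding gene bodies and 89.7% among genes that share no exon base with another gene, against 89.9% of all non-coding calls. A length or expression trend was argued against by a share that stayed 42.7 percentage points above that of protein-coding calls with the length trend removed, and 49.1 points above that of protein-coding calls matched on expression. Transcription past the ends of coding genes was argued against for genes on the same strand. There 6.5% of the rising genes started within 10 kb downstream of a coding gene against 19% of matched genes (permutation p = 1e-04 on the lower side, the smallest the draws can give). The rule fixed before the test named only a like share as evidence against, so the reading of a lower share was added to it. Starts downstream on the opposite strand were not examined, and the use of strand in counting was not given. Transcription away from coding promoters in the opposite direction may contribute and stays open, with 36.4% of the rising genes near a coding start against 30.5% of matched genes (permutation p = 0.089).

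A hypothesis that 1 growth-state axis moves genes both between replicate 1 and the rest and with the knockdown was tested by the correlation across genes of both differences, with the controls divided between them. The mean correlation was -0.085 (-0.071 and -0.098 in the 2 divisions), so the values gave no positive relation, and genes are not independent replicates.

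Regroupings of the 6 libraries were too few for a share under 0.05. Without the block, 10 of 10 splits gave at least the real count of changed genes (0, highest other 0) and of 2-fold changes (0, highest other 0), and 6 of 10 gave at least the 4 called lists, with a highest other of 16. The 4 splits that put both replicate 1 libraries in the same group called 12 to 16 lists, which points to the structure of the samples. With the block, 1 of the 4 splits that part the 3 pairs gave at least 2002 changed genes (highest other 0), 1 of 4 at least 260 2-fold changes (highest other 0) and 1 of 4 at least 14 lists (highest other 8).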
